A study of Mus musculus with 14 samples.

How the data were processed

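Cortex and hippocampus of mice aged 3 months were taken for sequencing of total RNA, extracted with RNeasy columns and made into libraries with a NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, TopHat2, Cufflinks and Cuffdiff and the genome build mm10. The versions of the last 3 tools, their settings and the gene annotation are not given in the sources used here.

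The deposited values are FPKM, fragments scaled by coding length and by the mapped total, with 1 value per condition and coding-sequence group, per the file headers, which carry Cuffdiff's column names. The authors pooled the replicates into these values, so the spread between samples cannot be computed and is seen through the authors' test alone. Each row also holds a deposited test statistic, used here as a score, and a deposited p-value and q-value, per the file headers. Rows marked as not tested by the authors were left out of counts and lists. The smallest deposited p-value is 5e-05. The hippocampus q-values equal a Benjamini-Hochberg adjustment over the tested rows of all 3 comparisons in that table to within 5.26e-07. The deposited cortex q-values differ from such an adjustment over the cortex table by up to 0.335, and the set of tests behind them is not given in the sources used here.

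The hippocampus table also holds 52696 rows that compare with 1 condition that no label describes, and these were not analysed here. In each table a set of 25 gene symbols had been turned into dates by a spreadsheet program and were left as they are. Where a control value is 0 no fold was computed. All log2 ratios were recomputed from the deposited FPKM as TRF2-depleted over control, without a pseudocount unless stated. Coordinates are those of the deposited locus, shifted to count from 1. A locus can span neighbouring genes.

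FPKM summed to 161467 and 159494 over the rows of control and TRF2-depleted cortex, and to 168036 and 168887 in hippocampus. The median log2 ratio of tested genes was -0.03 in cortex and 0.00 in hippocampus. The read depth of the samples is unknown, so no counting error is given. A large ratio is not by itself precise here. Among tested rows with at least a 2-fold ratio, 503 of 557 in cortex and 875 of 958 in hippocampus had a deposited p of 0.05 or more, and 70.9% and 65.5% of them belonged to genes with several rows, against 28.5% and 30.2% of all tested rows. For such genes the division of reads between rows can move a value, and for called genes with a printed log2 ratio the sum over rows is given where it differs.

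Samples were grouped by title, source name and genotype label. The sample whose title names hippocampus and whose tissue tag names cortex was placed in no group. Whether the authors' pooled values include it is not known here. Nothing in the labels ties samples to animals, so the p-values measure the spread between these samples, as the authors modelled it.

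The tests, the named-gene rule, 40 gene lists and the alternative settings were fixed before the data were examined. A row was called at a deposited q of 0.05 or less. For lists and comparisons of tissues each gene was represented by its tested row with the highest mean FPKM, with at least 1 FPKM in 1 group. Each list was described by its called members, by a Benjamini-Hochberg adjustment over the list alone, by its median log2 ratio with the percentile among 10000 random lists matched on mean expression in 20 bins, and by a one-sided Fisher's exact test of called members adjusted over lists. The percentile treats genes as independent and describes these libraries. Genes named in the text were Terf2, up to 10 called genes with the largest rise and 10 with the largest fall ranked after adding 0.1 FPKM, up to 4 called members of a list or 2 with the smallest p where none was called, and genes called in both tissues. Of these, members are named for lists the text describes, and genes named beyond the rule were chosen after their values were seen.

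The difference between tissues was to be tested with errors from the deposited statistic if a normal law of it gave the deposited p. It did not: that law gave 20 cortex rows with p under 0.05 against 595 deposited. Errors implied by the deposited p were used in its place, chosen after seeing the data, and at the smallest p such an error is an upper bound. The test of lists between tissues, over 36 lists with at least 3 members measured in both, was also added after seeing the data, as was a list of 20 myeloid genes used for Myo1f. Alternatives covered the q threshold, the minimum FPKM, a minimum fold of 1.5, genes in place of rows, the pseudocount, centring, summing over rows and the window around Terf2.

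Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calculation of the list percentile was checked on simulated values, drawn independently for each gene from a normal law with an SD of 0.25. Of 200 unchanged lists of 15 genes, 5.5% fell outside the central 95% of random lists with the 8658 cortex genes and 4.5% with the 9824 hippocampus genes. Such rates follow from this setting and do not cover lists whose genes vary together. Lists shifted by 0.2 on the log2 scale were found in 69.5% and 66.5% of draws.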

Results

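Total RNA from the cortex and the hippocampus of C57BL/6 mice aged 3 months was sequenced to compare control animals with animals depleted of TRF2, a protein of the shelterin complex that protects chromosome ends and is encoded by Terf2. The series title places the comparison in the question of how far neurons depend on functional telomeres, and its design text names a Cre recombinase driven by Dcx, a gene of newborn and migrating neurons. The labels describe 14 samples, with 4 control and 3 TRF2-depleted cortex samples and 3 control and 3 TRF2-depleted hippocampus samples. The labels of 1 further TRF2-depleted sample name both tissues, and it was placed in no group. Each condition has 1 pooled FPKM value per row in the authors' deposited table, so no error between replicates can be given for any value and the read depth of the samples is unknown. Of 26348 coding-sequence rows per tissue, the authors tested 9536 in cortex and 11054 in hippocampus. These covered 8658 and 9824 genes.

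In the cortex, the targeted gene was lower in the TRF2-depleted group without passing the authors' test. Terf2 lies on chromosome 8 from 107069402 to 107096685 (mm10), and its most abundant row was at 3.11 FPKM in control and 0.168 FPKM in TRF2-depleted cortex in the authors' deposited table, a log2 ratio of -4.21 with p = 0.105 and q = 0.576. The 2 other Terf2 rows were not tested by the authors. Summed over its rows, the gene had a log2 ratio of -4.15 in the authors' deposited table.

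Transthyretin (Ttr), the thyroid hormone carrier made by the choroid plexus, fell from 93.3 to 1.15 FPKM in TRF2-depleted cortex in the authors' deposited table (log2 ratio -6.34, q = 0.00864, chromosome 18 from 20665250 to 20674326). Among genes that fell about 2-fold in the authors' deposited table were Dusp8, a phosphatase of MAP kinases (9.01 to 4.02 FPKM), Crim1 (8.01 to 3.79 FPKM), the transcription factor Foxo6 (3.56 to 1.81 FPKM) and Herpud2 (11.4 to 5.92 FPKM). The authors' deposited table also lists Ltbp4 (log2 ratio -0.83, or -0.34 summed over its rows), Ier5l (-0.74), Lgi4 (-0.56), Mnt (-0.50) and B4galt2 (-0.48) among the 10 largest falls. The largest rises with a value above 0 in both groups were those of Myo1f, an unconventional myosin known from myeloid cells (1.45 to 5.78 FPKM, log2 ratio 1.99), and Serpina3n, a serine protease inhibitor raised in reactive astrocytes (4.29 to 10.7 FPKM, log2 ratio 1.32), apart from 1 row of Hmga1, as the authors' deposited table gives them. Asxl2 (log2 ratio 0.73, or 0.60 summed over its rows), Fam184a (0.66) and Pcp4l1 (0.42) rose by less in the authors' deposited table. S100a5 is listed at 0 in control and at 3.07 FPKM in TRF2-depleted cortex in the authors' deposited table, so no fold is given. The called row of Hmga1, at 0.0218 and 5.17 FPKM in the authors' deposited table, is 1 of 5 rows of that gene, whose summed log2 ratio was -0.20.

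At the deposited q of 0.05, 29 cortex rows passed, 7 higher and 22 lower in the authors' deposited table, while 595 rows had an unadjusted p under 0.05. The deposited cortex q is smaller than a Benjamini-Hochberg adjustment over the tested rows of that table gives. Adjusted within the table, 14 rows passed, 3 higher and 11 lower, and the 15 rows lost include Jund, Mnt, Hmga1, Asxl2, Fam184a, Pcp4l1, Lgi4 and B4galt2.

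Immediate early genes, which neurons switch on with activity, were lower in TRF2-depleted cortex. Of 24 measured members 3 fell and 21 did not pass. Arc, a regulator of synaptic strength, was 25.3% lower at 74.7 FPKM (log2 ratio -0.42, q = 0.00864), the clock gene Per1 from 19.1 to 14.3 FPKM (log2 ratio -0.41, q = 0.00864) and Jund from 25.7 to 20.2 FPKM (log2 ratio -0.35, q = 0.0437) in the authors' deposited table. Adjusted over the list alone, 12 members passed as lower and 1, Npas4, as higher. The list median of -0.27 lay below all 10000 random lists matched on expression (random range, holding the central 95%, -0.12 to 0.06). Called genes were enriched in the list (one-sided Fisher's exact test, adjusted p = 0.00223 over lists). The enrichment rests on 3 called members, of which Jund is lost when adjusted within the table, and was not recomputed without it. Beside the immediate early list, genes of striatal neurons had a median log2 ratio of 0.50 over 11 measured members. This lay above the random range of -0.20 to 0.15, with 11 of 11 higher. None of the 11 passed over all rows, and 5 passed adjusted over the list alone. Whether the cortex groups held equal amounts of striatal tissue was not tested. The rise of the striatal list is therefore not tied to TRF2 depletion alone. What lowered the immediate early list was not tested either, so its fall is not tied to TRF2 depletion alone. Lrrc10b had 1.68 and 3.32 FPKM (q = 0.0614) and Syndig1l 2.40 and 3.59 FPKM (q = 0.136) in control and TRF2-depleted cortex in the authors' deposited table.

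Myelin and oligodendrocyte genes had a median log2 ratio of -0.18 in cortex (percentile 0.1 of random lists), with 17 of 22 measured members lower and 0 past the threshold, although 5 had an unadjusted p under 0.05. The authors' deposited table gives Sox10 at 5.55 and 4.15 FPKM (q = 0.173) and Olig1 at 21.7 and 17.8 FPKM (q = 0.225). Thalamic genes (median 0.37, 4 measured) and interferon-stimulated genes (median 0.29, 5 measured) also lay above the random range, and both lay within it when each gene's rows were summed. Of 38 lists with a measured member, 5 had a median outside the range, against 1.9 by chance if genes were independent. Targets of p53 (median 0.02, 16 measured, percentile 80.84), DNA damage response genes (median -0.02, 13 measured, percentile 52.97) and microglia genes (median 0.01, 18 measured, percentile 71.88) lay within it, each with 0 members past the threshold. At an unadjusted p under 0.05 there were 0, 1 and 1 members in the authors' deposited table, and the means of the p53 and microglia lists (each -0.03, after adding 0.1 FPKM) were opposite in sign to their medians. In these lists Ddit4l (log2 ratio -0.73, p = 0.159), H2afx (-0.32, p = 0.0347) and C1qa (-0.32, p = 0.0459) had the smallest p in the authors' deposited table.

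**Figure D1:**
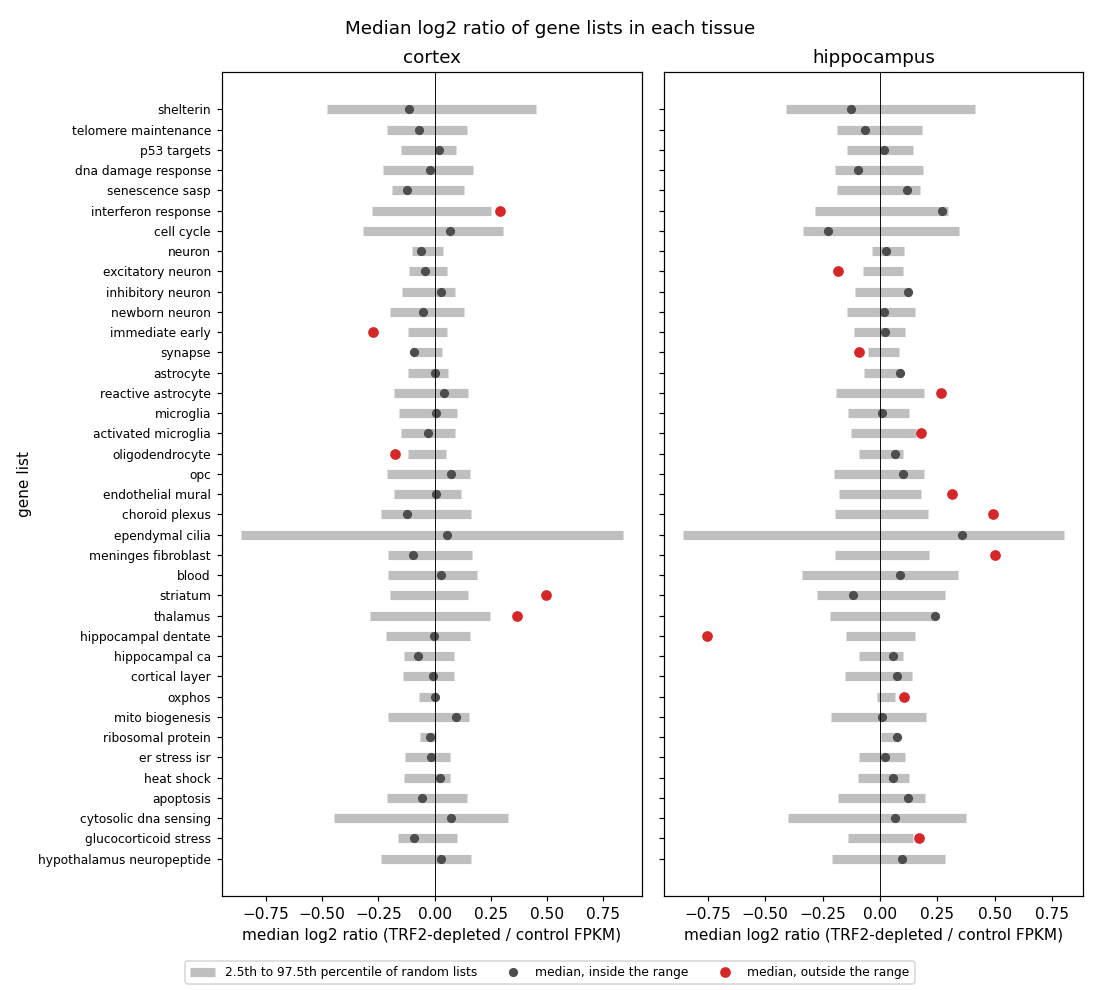
Median log2 ratio of TRF2-depleted over control FPKM for each gene list (vertical axis) in cortex (left) and hippocampus (right). Gray bars span the central 95% of 10000 random lists matched on mean expression, and red points are medians outside it, such as immediate early genes in cortex at -0.27 and dentate granule neuron genes in hippocampus at -0.75. The Y-linked list is left out of the plot.

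In the hippocampus, genes of dentate gyrus granule neurons were lower in the TRF2-depleted group. Of 15 measured members 6 fell, 0 rose and 9 did not pass. Desmoplakin (Dsp, chromosome 13 from 38151294 to 38198577) went from 3.27 to 1.16 FPKM (log2 ratio -1.49), Fam163b from 18.6 to 8.87 FPKM (-1.07), lactase (Lct) from 4.66 to 2.26 FPKM (-1.05) and Stxbp6 from 15.7 to 8.44 FPKM (-0.89) in the authors' deposited table. C1ql2 (log2 ratio -0.75) and C1ql3 (-0.55), secreted C1q-like proteins of synapses, complete the 6, all at q = 0.0301 in the authors' deposited table. Adjusted over the list alone 8 members passed, adding Prox1, a transcription factor of granule neurons (4.88 to 1.38 FPKM, q = 0.0764 over all rows), and calbindin (Calb1, 24.5 to 18.7 FPKM, q = 0.496 over all rows), with values from the authors' deposited table. The median log2 ratio was -0.75 against a random range of -0.15 to 0.15, 15 of 15 members were lower, and called genes were enriched (one-sided Fisher's exact test, adjusted p = 2.88e-12 over lists). CA pyramidal neuron genes had a median of 0.06 over 18 measured members (percentile 87.84) with 10 higher, 8 lower, 0 past the threshold and 2 at an unadjusted p under 0.05. These 2 went opposite ways in the authors' deposited table, Crym at 76.9 and 96.4 FPKM (p = 0.0095) and Chgb at 54.9 and 45.4 FPKM (p = 0.0328). The mean of the CA list was -0.31, opposite in sign to its median, and -0.03 without Gpr161, which had 2.45 and 0.0703 FPKM (p = 0.138) in the authors' deposited table.

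Terf2 was not tested in the hippocampus by the authors. Its most abundant row was at 1.04 and 0.526 FPKM in control and TRF2-depleted hippocampus in the authors' deposited table, a log2 ratio of -0.98, and the sum of its 3 rows gave -1.19.

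Outside the dentate list, peroxiredoxin 6 (Prdx6) fell from 29.8 to 11.9 FPKM (log2 ratio -1.32) and Mfsd6 from 9.74 to 4.51 FPKM (-1.11, or -1.05 summed over its rows) in TRF2-depleted hippocampus in the authors' deposited table. The authors' deposited table lists 4833420G17Rik (log2 ratio -0.85), Doc2b (-0.77), a calcium sensor of vesicle release, Cdr1 (-0.76) and Sema5a (-0.69) as the other genes that fell. Myo1f rose from 0.360 to 5.75 FPKM (log2 ratio 4.00, chromosome 17 from 33555707 to 33607764), the largest rise in the authors' deposited table at this threshold. Mier1 (log2 ratio 1.68, or 0.50 summed over its 4 rows), Zic1 (1.09), Cox7c (0.79), Vat1l (0.74) and Ptgds (0.68) also rose in the authors' deposited table. In total 18 rows of 18 genes passed, 6 higher and 12 lower, each at the smallest p in the authors' deposited table of 5e-05, and 540 rows had an unadjusted p under 0.05. At a q of 0.01 the count was 0.

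Genes of the meninges, the choroid plexus and blood vessels had medians above the random range in the same comparison. Meningeal and fibroblast genes had a median of 0.50 (17 of 17 measured members higher, percentile 99.97), with 1 past the threshold, the prostaglandin D synthase Ptgds (165 to 265 FPKM in the authors' deposited table), and 7 adjusted over the list alone. Choroid plexus genes had a median of 0.49 (11 of 11 higher, percentile 99.98), with 0 past the threshold, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone. Of these Igf2 had 7.94 and 12.3 FPKM (q = 0.107) and Kl 5.83 and 7.98 FPKM (q = 0.548) in the authors' deposited table. Blood vessel genes had a median of 0.31 (11 of 13 higher, percentile 99.95), with 0 past the threshold and 3 adjusted over the list alone. Thalamic genes lay just inside the range (median 0.24, 12 measured, percentile 97.37) and above it with a pseudocount of 1 (median 0.19, percentile 98.15). Over the 3 members with at least 5 FPKM the median was 0.02 (percentile 47.46). Zic1 was the 1 member past the threshold (2.12 to 4.51 FPKM in the authors' deposited table).

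Glutamatergic neuron genes had a median of -0.18 in hippocampus, below the random range of -0.07 to 0.10, with 18 of 20 measured members lower, 0 past the threshold and 4 at an unadjusted p under 0.05. Neurod1 had 7.04 and 4.77 FPKM (q = 0.415) and Neurod2 30.2 and 24.1 FPKM (q = 0.661) in the authors' deposited table. Synaptic genes had a median of -0.09 (30 measured, percentile 0.14) with 0 members past the threshold and 0 at an unadjusted p under 0.05, and the median was -0.04 and inside the range when rows were summed per gene. Nuclear-encoded oxidative phosphorylation genes had a median of 0.11, above a random range of -0.01 to 0.07. Of 54 measured members 45 were higher and 1, the cytochrome oxidase subunit Cox7c, passed the threshold (39.3 to 67.8 FPKM in the authors' deposited table). Ribosomal protein genes lay inside their range of 0.005 to 0.078 (median 0.075, 43 of 63 higher, percentile 97). Matched random lists thus lay mostly above 0 as well, so these shares are not to be read against an even split. Interferon-stimulated genes lay inside the range (median 0.27, 9 measured, percentile 96.46). They lay above it when rows were summed per gene (median 0.31, percentile 98.73), the opposite of the move in cortex. Of 39 lists with a measured member, 10 lay outside the range, against 1.95 by chance if genes were independent. Targets of p53 (median 0.02, 23 measured, percentile 61.16), DNA damage response genes (median -0.10, 17 measured, percentile 16.61) and microglia genes (median 0.01, 21 measured, percentile 60.44) lay inside it with 0 members past the threshold and 0, 1 and 0 at an unadjusted p under 0.05, and the mean of the p53 list (-0.02, after adding 0.1 FPKM) was opposite in sign to its median. The smallest p among the p53 targets was that of Cdkn1a, the cell cycle inhibitor p21 (2.58 and 1.79 FPKM, p = 0.0796), and among DNA damage genes that of Rad50 (2.23 and 1.60 FPKM, p = 0.0197), in the authors' deposited table.

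**Figure D2:**
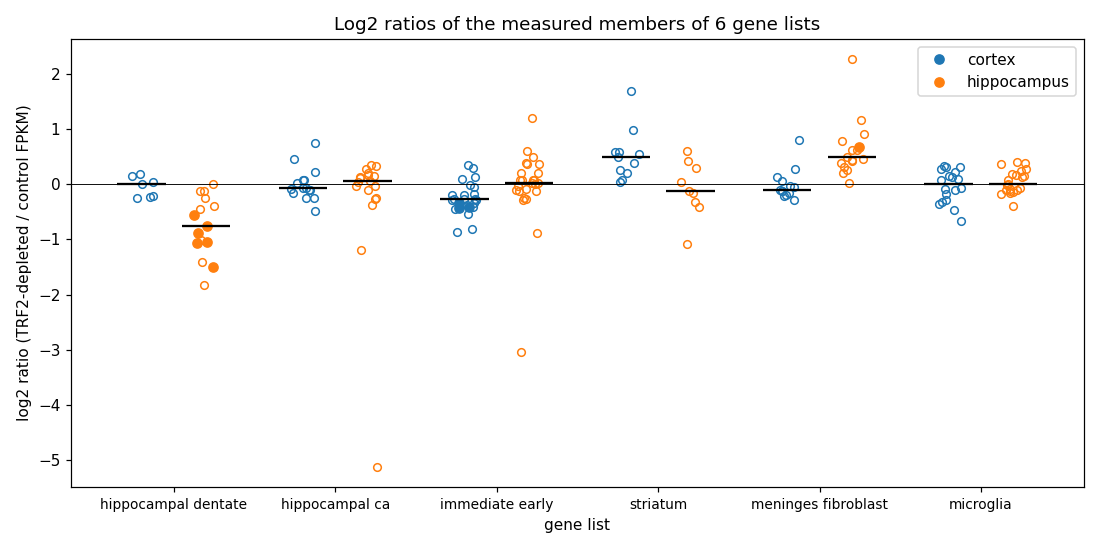
Log2 ratio of TRF2-depleted over control FPKM (vertical axis) for the measured members of 6 gene lists (horizontal axis) in cortex (blue) and hippocampus (orange). Each point is a gene, filled points passed a deposited q of 0.05, and black bars are list medians. The 15 dentate genes in hippocampus lie at or below 0, while the 18 CA genes center near 0.06.

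Across the tissues, Myo1f was the gene that rose in both, and no gene fell in both. Among 8332 genes tested in both, 5 had risen in cortex and 5 in hippocampus with 1 shared, against 0.003 for independent lists (one-sided Fisher's exact test, p = 0.003), and 22 and 8 had fallen with 0 shared, against 0.0211 (p = 1). The shared rise rests on 1 gene. The labels do not say whether both tissues came from the same animals, so it is no independent replication. The overlap test and the tests of differences between tissues treat the tissues as independent. The log2 ratios of 8330 genes were almost uncorrelated across genes (Pearson's r = 0.02, Spearman's rho = 0.03), and genes are not independent replicates. The fall of Ttr in cortex differed from its log2 ratio of 0.84 in hippocampus in the authors' deposited table (difference -7.18, 95% interval -10.31 to -4.05, adjusted p = 0.0285, with errors implied by the deposited p). Of the 38 called genes with a tested difference, Ttr was the 1 that passed, so a call in 1 tissue alone does not show that the tissues differ. The dentate list differed between tissues by a median of 0.65 (7 genes measured in both, percentile 99.98 of random lists), and the immediate early list by -0.37 (23 genes, percentile 0.01).

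Genes near Terf2 were examined because an engineered allele carries flanking sequence. Within 5 Mb, 0 of 76 measured genes in cortex and 0 of 90 in hippocampus passed the authors' test (two-sided Fisher's exact test, p = 1 in both), while 3 and 6 had an unadjusted p under 0.05 in the authors' deposited table. Their median log2 ratio was -0.09 in cortex (percentile 1.49 of random lists) and -0.03 in hippocampus (percentile 21.24). The cortex median lay inside the random range with a 2 Mb window (-0.09, percentile 7.11) and below it with a 10 Mb window (-0.09, percentile 1.91).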

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

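The tests of differences between tissues, the share of dentate genes that were lower and the test of the genes around Myo1f were chosen only after the results were seen. Too few values are in the tables to look for single samples that stand apart.

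The log2 ratio of Ttr differed between tissues by -7.18 (cortex minus hippocampus), and the median of the choroid plexus list by -0.60 over 4 genes measured in both (percentile 0.17 of random lists), with medians of -0.12 in cortex and 0.47 in hippocampus, where 20 of 21 choroid plexus genes apart from Ttr were higher (median 0.51). A candidate explanation is less choroid plexus in the TRF2-depleted cortex samples. It predicted that other choroid plexus genes would fall as well, and 21 of 21 others with at least 0.1 FPKM in 1 group were lower in cortex, with a median log2 ratio of -2.18. Of these 21, 3 were tested by the authors, most lay near the floor, and Enpp2, Igfbp2 and Igf2, which other brain cells express too, had log2 ratios of -0.07, -0.13 and -0.12 (summed over rows, -0.11 for Enpp2 and -0.37 for Igf2) in the authors' deposited table. In hippocampus 11 of 11 measured members were higher (percentile 99.98). That argues against an effect of TRF2 depletion that lowers choroid plexus genes in both tissues alike. An effect on the choroid plexus limited to the cortex samples stays open, as untested.

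The dentate list differed between tissues by a median of 0.65, with 7 of 7 genes lower in hippocampus than in cortex by their log2 ratio. The medians of these 7 genes were -0.0023 in cortex and -0.89 in hippocampus. The difference thus largely repeats the fall in hippocampus and is no separate support for it. Dilution by tissue from beside the hippocampus was predicted to lower CA genes about as much. The CA median lay 0.81 above the dentate median (error 0.19, taken over genes, not samples), and 10 of 18 CA genes were higher. That argues against tissue without CA genes as the whole account. It does not cover cortical tissue, since 15 of 20 listed CA genes but 7 of 18 dentate genes were measured in cortex. The means differed by 0.45 (error 0.33), within 2 errors, with the CA mean carried by Gpr161. Genes of adjoining tissue were higher in the same samples (medians of 0.50 for meninges, 0.49 for choroid plexus and 0.31 for blood vessels). The thalamic median of 0.24 lay inside the random range, but above it with a pseudocount of 1. Glutamatergic and synaptic genes were lower (medians of -0.18 and -0.09), while the median for genes of neurons in general was 0.03. The mean of that general list was -0.14 after adding 0.1 FPKM, opposite in sign to its median. Synaptic genes also had a median of -0.09 in cortex, inside the random range (percentile 3.91). Some adjoining tissue therefore stays open as a part of the dentate fall, and cortical tissue was not tested. Fewer granule neurons per amount of tissue would lower most members, and 100% of the 15 were lower, but this was known in large part when the test was chosen and separates neither loss of cells from dissection nor either from lower expression per cell. For fewer newborn neurons the list median lay at percentile 58.68, past the bound set beforehand for arguing against it. Yet 6 of its 13 members (46.2%) were lower and 7 higher. Adjusted over the list alone, 1 member, Neurod1, passed as lower and 0 as higher. The fall predicted was small, to below -0.14, whereas the CA list and, for Myo1f below, the microglia list were set against far larger shifts. A median near 0 over members that go both ways was therefore taken to decide nothing here, a reading adopted after the value was seen. An effect of TRF2 depletion on granule neurons may remain and was not tested.

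The median of the glutamatergic neuron list differed between tissues by 0.18 (percentile 99.94 of random lists) and that of the immediate early list by -0.37 (percentile 0.01). These 2 lists and the choroid plexus and dentate lists were the 4 that passed an adjustment over the 36 lists compared. Tmsb10 differed by -0.75 (adjusted p = 0.0285), with log2 ratios of -0.27 in cortex and 0.48 in hippocampus in the authors' deposited table, neither past the threshold there, and it no longer passed with errors from the test statistic (adjusted p = 0.9995).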

How the results depend on the processing

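Both settings for the difference between tissues were chosen after seeing the data. No paired analysis was possible because the tables hold 1 pooled value per condition, and for the same reason leaving out each replicate, a replicate block and other splits of the samples were not run. The cortex count of 29 became 14 at a q of 0.01, 65 at 0.10, 14 with at least 1 FPKM, 12 with at least 5 FPKM, 13 with a 1.5-fold minimum, 14 over genes and 2 with a normal-law p. A filter at 1 FPKM removed no tested row, so the fall to 14 comes from adjusting within the table. The settings at 5 FPKM and over genes adjust within the table as well, so their fall from 29 is not separated from that step. The q thresholds and the fold minimum change the rule alone. The normal law gives larger p, which are adjusted within the table as well, so its fall to 2 is not separated from that step. The hippocampus count of 18 became 0 at a q of 0.01, since its smallest q is 0.0301, and 2 with a normal-law p, and lay between 17 and 26 otherwise. The Terf2 log2 ratio became -4.15 summed over rows and -1.82 with a pseudocount of 1 in cortex, and -1.19 and -0.42 in hippocampus. The median of genes near Terf2 in hippocampus turned from -0.03 to 0.0054 with a 10 Mb window, which takes in Vat1l at 7.14 Mb (Fisher's exact test, p = 0.171). The correlation between tissues became -0.0119 with at least 5 FPKM, and the cause was not tested. The count of genes that differed between tissues was 2 and became 1 with errors from the test statistic, which kept Ttr and lost Tmsb10. For lists, centring and no minimum FPKM moved no percentile and are left out, and under the other settings 142 of 151 combinations of list and setting in cortex and 150 of 155 in hippocampus kept their side of the random range, 0 changed direction after lying outside it, and the dentate and immediate early lists kept theirs. Unknown read depth limits what can be said of low genes such as Terf2.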

Other observations

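The test of the genes around Myo1f was chosen only after part of its result was seen, and the test of other myeloid cells was added after the Myo1f and microglia results, with its genes and bounds set before its values were seen. In TRF2-depleted hippocampus reactive astrocyte genes had a median log2 ratio of 0.27 (12 measured, percentile 99.57) with 0 past the threshold and 2 at an unadjusted p under 0.05. Serpina3n is listed there at 0 and 4.08 FPKM (p = 0.158), beside its rise in cortex, in the authors' deposited table. Activated microglia genes (median 0.18, percentile 98.64) and glucocorticoid-responsive genes (median 0.17, percentile 98.81) also lay above the random range in hippocampus with 0 members past the threshold, and the activated microglia list lay inside it with a minimum of 5 FPKM (median 0.14, percentile 94.38). Heat shock genes, which can move with dissection, lay inside it in both tissues (percentiles 86.3 and 78.72). In hippocampus 12 of the 15 measured were higher and 3 lower, and 2 of the 15 had an unadjusted p under 0.05. Of these 15, Hspa1b passed as higher adjusted over the list alone. Medians inside the range do not show that dissection or RNA quality was equal between groups.

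Y-linked genes, which depend on the balance of sexes, had a median log2 ratio of -1.03 over 3 measured members in TRF2-depleted hippocampus, inside the random range (percentile 4.475), with 0 past the threshold and 0 at an unadjusted p under 0.05. The authors' deposited table gives Ddx3y at 4.23 and 2.76 FPKM (p = 0.639), Eif2s3y at 1.60 and 0.179 FPKM (p = 0.346) and Uty at 1.87 and 0.917 FPKM (p = 0.337). In cortex none of the 4 listed genes was tested, with Ddx3y at 2.05 and 1.99 FPKM, Eif2s3y at 1.66 and 1.29 FPKM, Uty at 0.567 and 0.000262 FPKM and Kdm5d at 0.42 and 0.50 FPKM in the authors' deposited table. The sexes of the animals are not given in the sources used here.

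Myo1f rose in both tissues, by 1.99 and 4.00 on the log2 scale in the authors' deposited table. More microglia would raise the microglia list by about as much, but the larger of its 2 medians was 0.011, and the activated microglia list, at -0.03 in cortex and 0.18 in hippocampus, also stayed far below, which argues against that explanation. More of other myeloid cells would bring their abundant transcripts, but over 20 genes the larger of the 2 median FPKM rises was 0.428% of that of Myo1f and 0 genes rose by as much, which argues against it as well, although most of these genes lay near the floor and Coro1a, which other cells express too, was 3.02 and 2.46 FPKM higher. A change reaching its chromosomal neighbourhood would move genes within 500 kb, but 0 of 23 in cortex and 0 of 24 in hippocampus were called, and the higher of the 2 percentiles of their median size of change was 71.79, which argues against a change across the neighbourhood. Adamts10, which lies just before Myo1f, was not tested in cortex, at 0.0108 and 0.0068 FPKM in the authors' deposited table. It thus did not rise with Myo1f there, but a median over the window cannot exclude a change limited to the nearest genes. A change at Myo1f alone, such as an altered allele or reads from an engineered construct, and a response of Myo1f to TRF2 depletion stay open as hypotheses, since the tables hold no value per sample to test them.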
